A study of Mus musculus with 6 samples.

How the data were processed

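RNA was measured in 6 libraries of sorted mouse keratinocytes, from the denervated left and the normal right back skin of 3 animals. Per the labels' protocols, the mice carried an Lgr6 knock-in that expresses GFP and an inducible Cre together with a Cre-dependent tdTomato reporter, received 20 µg of tamoxifen on postnatal day 42, and were sampled 4 weeks after surgery. Cells were stained for CD49f (Itga6) and sorted, RNA was column-purified, and poly(A) libraries were made with a strand-specific kit, per the labels' protocols. The same protocols describe the removal of nerves on the left and intact nerves on the right, and mention no sham dissection of the right side.

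The submitters' processing notes name STAR 2.6.1a, Salmon 0.11.2 and the mm10 genome, without saying which made which values. The gene annotation, the tool that made the count matrix and its strand setting are not given in the sources used here. The deposited matrix holds raw whole-number counts for 24982 rows, of which 26 have names that a spreadsheet turned into dates, and 2 such names occur in 2 rows each. These rows stayed in the totals and tests and are not named. The deposited per-sample files hold estimated counts (expected counts from Salmon, not whole), TPM and lengths per gene, per the file headers. A deposited table holds TPM for all 6 libraries. The authors' own comparison is a deposited table of log2 fold changes with p-values, adjusted p-values and the mean normalised signal (counts). Its fold changes are denervated over normal, checked against group means. Mitochondrially encoded genes are not in the count matrix used here, so that share was not computed, and Flg and the constant genes of the T cell receptor were not analysed here.

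Groups and animal numbers came from the sample titles. The numbers pair the samples because both sides come from the same mouse, per the labels' protocols. As a check, deviations from the group means (log2 CPM) correlated at 0.356, 0.361 and 0.443 for the 3 same-animal pairs of libraries and between −0.278 and −0.0407 for the other 6, across genes, which are not independent. Deviations cancel within a group, so positive same-animal values make the others negative on average. The negative values therefore add nothing to the same-animal ones. Pearson correlations of log2 CPM between libraries ran from 0.971 to 0.989 across genes. Libraries of 1 group differed by more than sampling noise (chi-square per degree of freedom from 12.2 to 18.0), so none was a duplicate. The labels give no sequencing batch or date.

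The main test, the gene lists and the rule for named genes were fixed before the data were examined. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) of denervated against normal over all 6 libraries with TMM factors and filterByExpr (minimum count 10, minimum total 15), which kept 12310 genes. It had no term for the animal, since the submitters' design was not stated. The same test with the animal as a block was planned with it and is given beside it wherever it changes a call, and called the paired fit. P-values were adjusted by Benjamini-Hochberg and called below 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change over the square root of F. The common biological coefficient of variation was 0.140 without and 0.0920 with the block. Beside these ran DESeq2 1.42.0 and limma 3.58.1 on log2(TPM + 1) for genes with a mean TPM of at least 1, so that fold changes of low genes are understated there. Adjusted p-values that DESeq2 gave as NA stayed NA.

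The 39 gene lists covered keratinocyte compartments, signalling, cell cycle, stress and markers of other cells that the gate could hold. The 36 lists with at least 3 tested members entered camera on log2 CPM (prior count 2) with a preset correlation of 0.01, adjusted over the lists. The mitochondrially encoded, adipocyte and erythroid lists had fewer than 3. Estimated correlation and fry were alternatives. With an estimated correlation none of the 36 lists was called, with or without the block. Marker sums of other cell types were CPM on library totals, tested by an exact permutation test.

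The rule for named genes took the 12 largest changes per direction among genes that passed, with a mean of at least 1 CPM and the same direction in 3 animals, leaving out predicted genes. Some genes that the rule picks are not reported here. Where fewer passed, the genes next by p filled up to 5. From each list it took up to 4 members that passed or the 2 with the smallest p, and Lgr6, Itga6, Krt5 and Krt14 always. Since no gene passed without the block, the rule was applied a second time to the paired fit, a step chosen after the counts were seen. Coordinates come from GENCODE annotation of the mm10 assembly by gene symbol, which matched 12198 of the tested genes.

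Alternatives were DESeq2 size factors, library totals, other filters, the estimated counts rounded to whole numbers, other thresholds, DESeq2, limma on TPM, and leaving out each library or animal. Correction for gene length, thinning of libraries to the smallest total and further settings of the blocked fit were chosen after seeing the data. On simulated counts for 12310 genes with 200 changed, drawn from the means and library sizes of these libraries, edgeR without the block recovered 46% of 1.5-fold and 78% of 2-fold changes, with 21 false among 145 calls. On the same counts DESeq2 without the block recovered 56% and 80%, with 31 false among 167 calls. With animal effects kept, the blocked edgeR fit recovered 69% and 79%, with 5 false among 153 calls. The unblocked edgeR fit recovered 24% and 61% of those changes. In the simulated lists camera with the preset correlation found the planted list and called 0 of 35 others, while an estimated correlation gave the planted list an adjusted p of 0.276 and fry 0.246. Genes were drawn independently there, without animal effects, and the other lists were random. The simulation therefore cannot show how often camera falsely calls lists whose genes vary together, as in the real libraries. Depth limits low genes, as 3 counts equal 0.115 to 0.312 CPM, and this floor covers counting error only, since PCR copies are not independent molecules.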

Results

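Poly(A) RNA was sequenced from epidermal stem cells of mouse back skin in 6 libraries, 3 from skin without its nerves and 3 from skin with its nerves. Cells carried a red fluorescent reporter, tdTomato, that tamoxifen switches on in cells expressing Lgr6, a receptor for R-spondins, and in their descendants. They were sorted for this label and for Itga6 (CD49f), the integrin that anchors basal keratinocytes to the basement membrane. Each of 3 animals, numbered 890, 892 and 899, gave 1 library from the left side, whose cutaneous nerves had been dissected out 4 weeks earlier, and 1 from the right side, whose nerves were left in place. In the order of these animals, the normal libraries held 26167593, 20724439 and 13801154 counts and the denervated libraries 9610071, 14021730 and 13232950. Totals were lower on the denervated side in 3 of 3 animals, a difference that an exact two-sided permutation test did not call (p = 0.2, where 3 against 3 libraries cannot go below 0.1). A floor of 3 counts corresponded to 0.115 to 0.312 CPM (counts scaled to the library total), depending on the library, for counting error only. Levels of genes are given in CPM after TMM scaling, as mean ± SD over 3 libraries per side (n = 3).

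None of the genes behind the sort passed the test. Lgr6 (chromosome 1, 134983301 to 135105276, minus strand, mm10) stood at 97.3 ± 8.65 CPM on the normal side and 93.8 ± 14.5 CPM on the denervated side (log2 fold change −0.05 ± 0.12 SE, adjusted p = 0.900, edgeR). It was lower in animal 890 and higher in the other 2 animals. Without animal 890, the log2 fold change of Lgr6 was 0.11. Itga6 stood at 1425 ± 17.9 and 1624 ± 37.2 CPM and was higher on the denervated side in 3 of 3 animals, but did not pass (log2 fold change 0.19 ± 0.08 SE, adjusted p = 0.363). The basal keratins were abundant on both sides. Krt5 stood at 19593 ± 704 and 19833 ± 2065 CPM and Krt14 at 12569 ± 144 and 13872 ± 1834 CPM, with adjusted p = 0.967 and 0.664. The log2 fold change of Krt5 was 0.02 with TMM factors and −0.04 with library totals.

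The comparison of denervated with normal skin bears on the dependence of Lgr6-lineage stem cells on cutaneous nerves. The labels describe no sham dissection on the right, so loss of nerves, surgery and body side cannot be told apart. With each animal's 2 sides compared, the denervated cells held more mRNA for Nrg1, the ErbB ligand neuregulin 1, which rose 2.02-fold. The collagenase gene Mmp13 rose 2.87-fold, the stromelysin genes Mmp10 and Mmp3 2.86-fold and 1.60-fold, the AP-1 subunit gene Fosl1 1.55-fold, and the hyaluronan receptor gene Cd44 1.46-fold. Genes that fell included Axin2, a feedback inhibitor and target of canonical Wnt signalling (1.56-fold lower), Hes1, a target of Notch (1.67-fold lower), and Gadd45g, a stress-induced growth arrest gene (1.72-fold lower). Changes were mostly small, with a median absolute log2 fold change of 0.44 among the genes that passed. In edgeR these calls rest on the pairing of sides within an animal, and that of Cd44 was lost without animal 890. DESeq2 called Nrg1, Fosl1, Cd44 and Axin2 without that pairing as well, and did not call Hes1 with or without it. On simulated counts, however, DESeq2 without the pairing gave 31 false among 167 calls, so its calls are a weak check.

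Without a term for the animal, edgeR's quasi-likelihood test called 0 of 12310 genes at an adjusted p below 0.05, with a smallest adjusted p of 0.137. At an unadjusted p below 0.05 there were 1537 genes, 930 of them higher on the denervated side, where chance alone gives about 615.5 on average. How far that count varies by chance when genes vary together was not measured. DESeq2 without that term called 365 genes, 336 higher and 29 lower. Limma on log2(TPM + 1) called 1, Mir1192, named after its values were seen (−5.95, lower). That value rests on TPM alone, and edgeR without the block on the estimated counts called 0 genes. Whether it reflects a change of this microRNA, in libraries of poly(A) RNA, was not tested. With the animal as a block, edgeR called 426 genes, 355 higher and 71 lower on the denervated side. The blocked fit with library totals in place of TMM factors called 290 genes, 172 higher and 118 lower. The share of higher genes was then 59.3% rather than 83.3%. Only 243 of the 426 genes were called again there, although all 426 kept their sign, so many calls rest on the TMM factors. Of the 426 genes, 425 moved the same way in 3 of 3 animals, where chance gives 25%, although the test itself selects such genes. A total of 409 had an unadjusted p below 0.05 without the block. Single animals weighed on the count. The unblocked fit called 42 genes without the normal library of animal 899, and the blocked fit called 248 genes without animal 892 and 976 without animal 899.

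Of 49 tested neurotrophic factors and axon guidance genes, 3 rose in the paired fit, Nrg1 and Epha4 among them, and camera did not call the list (adjusted p = 0.955). Nrg1 (chromosome 8, 31814551 to 32884029, minus strand) rose from 36.0 ± 11.5 to 71.7 ± 16.9 CPM (paired log2 fold change 1.02 ± 0.12 SE, adjusted p = 0.00196; 0.165 without the block). Its log2 difference was 1.38 in animal 890, 1.04 in animal 892 and 0.62 in animal 899. Epha4, an ephrin receptor, rose from 193 ± 16.0 to 265 ± 28.5 CPM. Of 25 tested receptors for neuropeptides and neurotransmitters 1 passed, Trpv3, a heat-gated channel of keratinocytes, which rose from 32.9 ± 6.09 to 49.5 ± 15.4 CPM. Ngfr, the low-affinity receptor of neurotrophins, stood at 26.4 ± 3.37 and 20.5 ± 5.05 CPM (adjusted p = 0.221 in the paired fit).

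**Figure D1:**
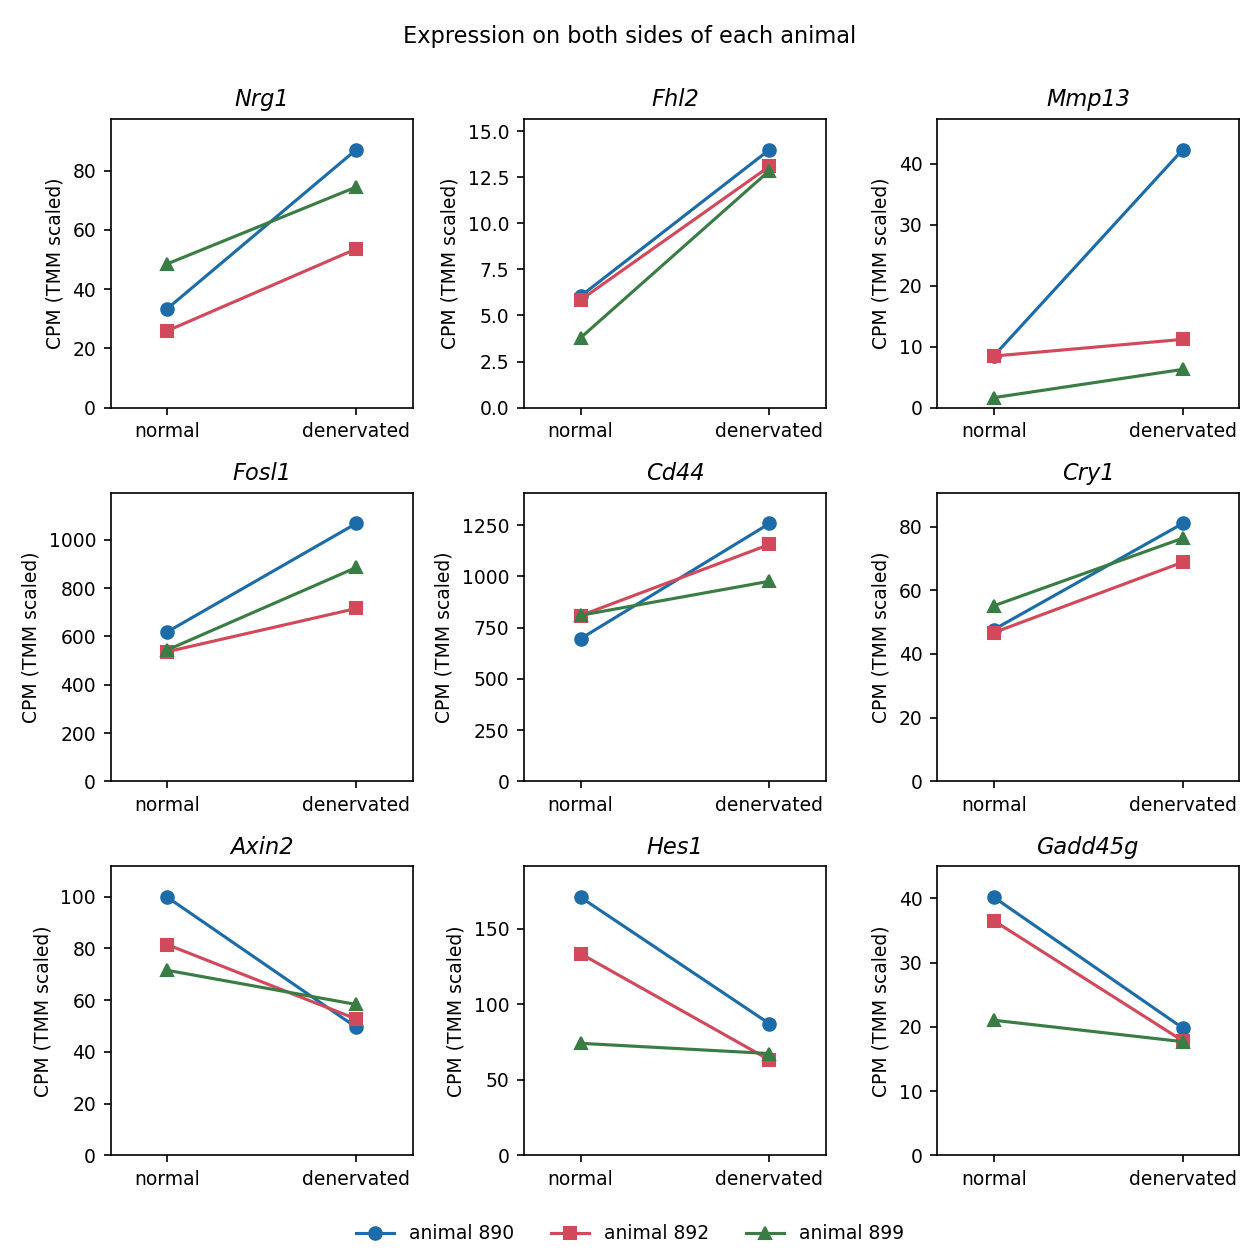
CPM after TMM scaling (vertical axes, starting at 0) of 9 genes on the normal and the denervated side, with 1 line per animal (890, 892 and 899). Nrg1, Fhl2, Mmp13, Fosl1, Cd44 and Cry1 are higher and Axin2, Hes1 and Gadd45g lower on the denervated side in 3 of 3 animals, and denervated Mmp13 reaches 42.3 CPM in animal 890 against 11.2 and 6.28 CPM in the other 2.

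Among 32 tested genes of wound-associated keratinocyte activation, 9 rose in the paired fit and none fell. The collagenase Mmp13 (6.20 ± 3.94 to 19.9 ± 19.5 CPM) and the stromelysins Mmp10 (2.62 ± 0.790 to 7.66 ± 3.36 CPM) and Mmp3 (38.1 ± 15.8 to 62.2 ± 30.7 CPM) lie in a gene cluster on chromosome 9, between position 7272514 and position 7510240. Without animal 890 the paired log2 fold changes of Mmp13 and Mmp10 were 0.95 and 1.00, against 1.52 and 1.52 with it. Fosl1 rose from 567 ± 45.5 to 889 ± 176 CPM, and Sprr1a, a cornified envelope precursor, from 136 ± 10.3 to 201 ± 33.4 CPM. Adjusted over the list alone, 17 members passed, 15 higher and 2 lower. The list as a whole was higher (mean log2 fold change 0.31, camera adjusted p = 0.00321 without and 0.000221 with the block). With an estimated correlation between genes it was not called (adjusted p = 0.992). Leaving 1 library out of the unblocked test keeps its animal on 1 side only, so differences between animals enter the mean. There the mean of the list was −0.01 (adjusted p = 0.234) without the normal library of animal 899. It was −0.07 (adjusted p = 0.422) without the denervated library of animal 890. That library stood apart on the first principal component of log2 CPM (36.5% of the variance), at −37.6, with the next lowest, the normal library of the same animal, at −9.73. With the block, the list was called without each animal in turn (means 0.20, 0.50 and 0.26).

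Genes of adhesion and of follicle compartments moved in part. Of 26 tested genes of basal keratinocytes and the basement membrane, 3 rose in the paired fit. Among them were Cd44 (771 ± 65.5 to 1130 ± 143 CPM) and the collagen-binding integrin gene Itga2 (134 ± 13.3 to 182 ± 19.0 CPM), the last at a paired log2 fold change of 0.28 without animal 890 against 0.44 with it. Of 26 genes of the bulge and hair germ, 3 rose, namely the transcription factor genes Runx1 (paired log2 fold change 0.68 ± 0.13 SE), Nfatc1 (0.44 ± 0.07 SE) and Sox9 (0.35 ± 0.09 SE). Of 20 genes of the isthmus and infundibulum, where Lgr6 cells of the follicle lie, Plet1 (0.63 ± 0.11 SE) and the tight junction gene Cldn1 (0.40 ± 0.10 SE) rose, Plet1 by 0.42 without animal 890. Of 38 suprabasal differentiation genes, the lipoxygenase gene Aloxe3 (0.65 ± 0.15 SE) and the repressor gene Prdm1 (0.56 ± 0.13 SE) rose, Aloxe3 by 0.43 without animal 890. No member passed among 12 tested genes of the hair shaft and inner root sheath, where Foxn1 and Krt25 had the smallest p, or among 7 of the touch dome and Merkel cells, where Krt17 and Tnc did.

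Sebaceous gland genes were lower as a list (mean log2 fold change −0.35, camera adjusted p = 0.00832 without and 0.000944 with the block). With an estimated correlation the adjusted p was 0.992. Of the 21 tested members, 3 fell in the paired fit, which were the desaturase gene Scd3 (−1.64 ± 0.38 SE), the fatty acid binding protein gene Fabp5 (−0.43 ± 0.11 SE) and the triglyceride synthesis gene Dgat2 (69.7 ± 6.68 to 51.9 ± 5.62 CPM). The remaining called member, Prdm1, rose. Adjusted over the list alone, 6 passed, 1 higher and 5 lower. Scd3 has close relatives, and whether their reads were kept apart was not tested. In the estimated counts the paired log2 fold change of Scd3 was −1.65. The call of the list was lost without the normal library of animal 899 (adjusted p = 0.170) and without animal 899 (adjusted p = 0.0563, and 0.0645 with the block). Elovl3, a fatty acid elongase gene, stood at 3.49 ± 0.582 and 1.78 ± 0.410 CPM and did not pass.

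Signalling lists moved in single members. Of 31 tested Wnt and R-spondin genes, 2 fell in the paired fit and none rose. Axin2 went from 84.3 ± 14.3 to 53.5 ± 4.46 CPM (paired log2 fold change −0.64 ± 0.11 SE, adjusted p = 0.0103) and the ligand gene Wnt3a from 19.7 ± 0.818 to 13.6 ± 2.26 CPM. Of 17 Notch genes, Hes1 fell (126 ± 48.8 to 72.5 ± 12.8 CPM), with a log2 difference of −0.97 in animal 890, −1.08 in animal 892 and −0.14 in animal 899. Hes1 was not called by DESeq2 without the block (adjusted p = 0.186) or with it (0.116), nor in the authors' deposited table (0.105). The coactivator gene Maml1 rose (0.34 ± 0.08 SE). Of 33 TGF-beta and BMP genes, 5 passed, 3 higher and 2 lower. Among them, Smad3 (0.39 ± 0.08 SE) and the receptor gene Tgfbr2 (0.35 ± 0.07 SE) rose, and the BMP target Id3 (−0.53 ± 0.13 SE) fell, Id3 with −0.33 without animal 892. The other lower member, Id1, named after its values were seen, fell as well (−0.67 ± 0.16 SE). None of 14 Hedgehog genes passed, with Ptch1 at 43.3 ± 1.76 and 39.0 ± 6.44 CPM and Cdon with the next smallest p.

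No cell cycle list was called. None of 35 tested genes of S phase passed, with Cdc45 and E2f1 closest, and none of 35 of mitosis, with Bub1 and Kif20a closest. Camera gave an adjusted p of 0.169 for S phase, lower on the denervated side, and 0.0749 for mitosis, higher. Of 21 inhibitors of the cell cycle, Gadd45g (32.6 ± 10.2 to 18.4 ± 1.19 CPM) and Gadd45b (383 ± 66.4 to 280 ± 28.0 CPM) fell in the paired fit.

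Stress and metabolic lists were mixed. The unfolded protein response list was higher (mean log2 fold change 0.19, camera adjusted p = 0.00240 without and 0.000221 with the block), but not with an estimated correlation (adjusted p = 0.992). Of its 24 members, 3 rose in the paired fit, the transcription factor gene Xbp1 (0.40 ± 0.08 SE), the asparagine synthetase gene Asns (0.44 ± 0.10 SE) and the glutathione-degrading enzyme gene Chac1 (0.74 ± 0.18 SE). Without animal 890, Asns stood at 0.29. Adjusted over the list alone, 7 passed, all of them higher. The interferon response list was lower (mean log2 fold change −0.27, camera adjusted p = 0.0127 without and 0.00158 with the block). That call was lost with an estimated correlation (adjusted p = 0.992), with no filter on low counts (adjusted p = 0.0826), and without the normal library of animal 890 (0.0717) or the denervated library of animal 892 (0.107) or 899 (0.102). It was also lost without animal 892 (0.153, and 0.136 with the block). Of its 24 members, Irf1 fell (357 ± 53.6 to 261 ± 46.9 CPM) and the others did not pass.

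Of 35 genes of the response to dissociation, 4 passed in the paired fit. Klf6 (0.44 ± 0.09 SE), Egr3 (0.35 ± 0.08 SE) and Fosb (0.40 ± 0.10 SE) rose and Socs3 fell (−0.59 ± 0.14 SE). Of 31 cytokine and chemokine genes, Nfkb2 rose (0.31 ± 0.07 SE). Of 27 NRF2 targets, Txnrd1 (0.40 ± 0.08 SE) and Srxn1 (0.48 ± 0.12 SE) rose. Of 33 hypoxia and glycolysis genes, Hk2 rose (0.33 ± 0.08 SE) and Ddit4 fell (−0.44 ± 0.11 SE), with −0.24 without animal 892. Of 23 cholesterol genes, Sc5d rose (0.48 ± 0.10 SE). Of 19 circadian clock genes, the repressor gene Cry1 rose from 49.8 ± 4.60 to 75.4 ± 6.14 CPM and Per1 fell from 279 ± 25.4 to 219 ± 19.2 CPM. None of 41 genes of oxidative phosphorylation passed, and none of 73 cytosolic ribosomal protein genes. Over other splits of the same 6 libraries into 3 and 3, camera called 5 to 12 lists, against 4 for denervated and normal. In 7 lists, none of them called, the sign of the mean differed from that of the test in the unblocked or the paired fit, namely those of suprabasal differentiation, the dissociation response, touch dome, TGF-beta and BMP, circadian clock, fibroblasts, and Schwann cells and neurons. Median and mean differed in sign in the suprabasal, neurotrophic and endothelial lists.

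**Figure D2:**
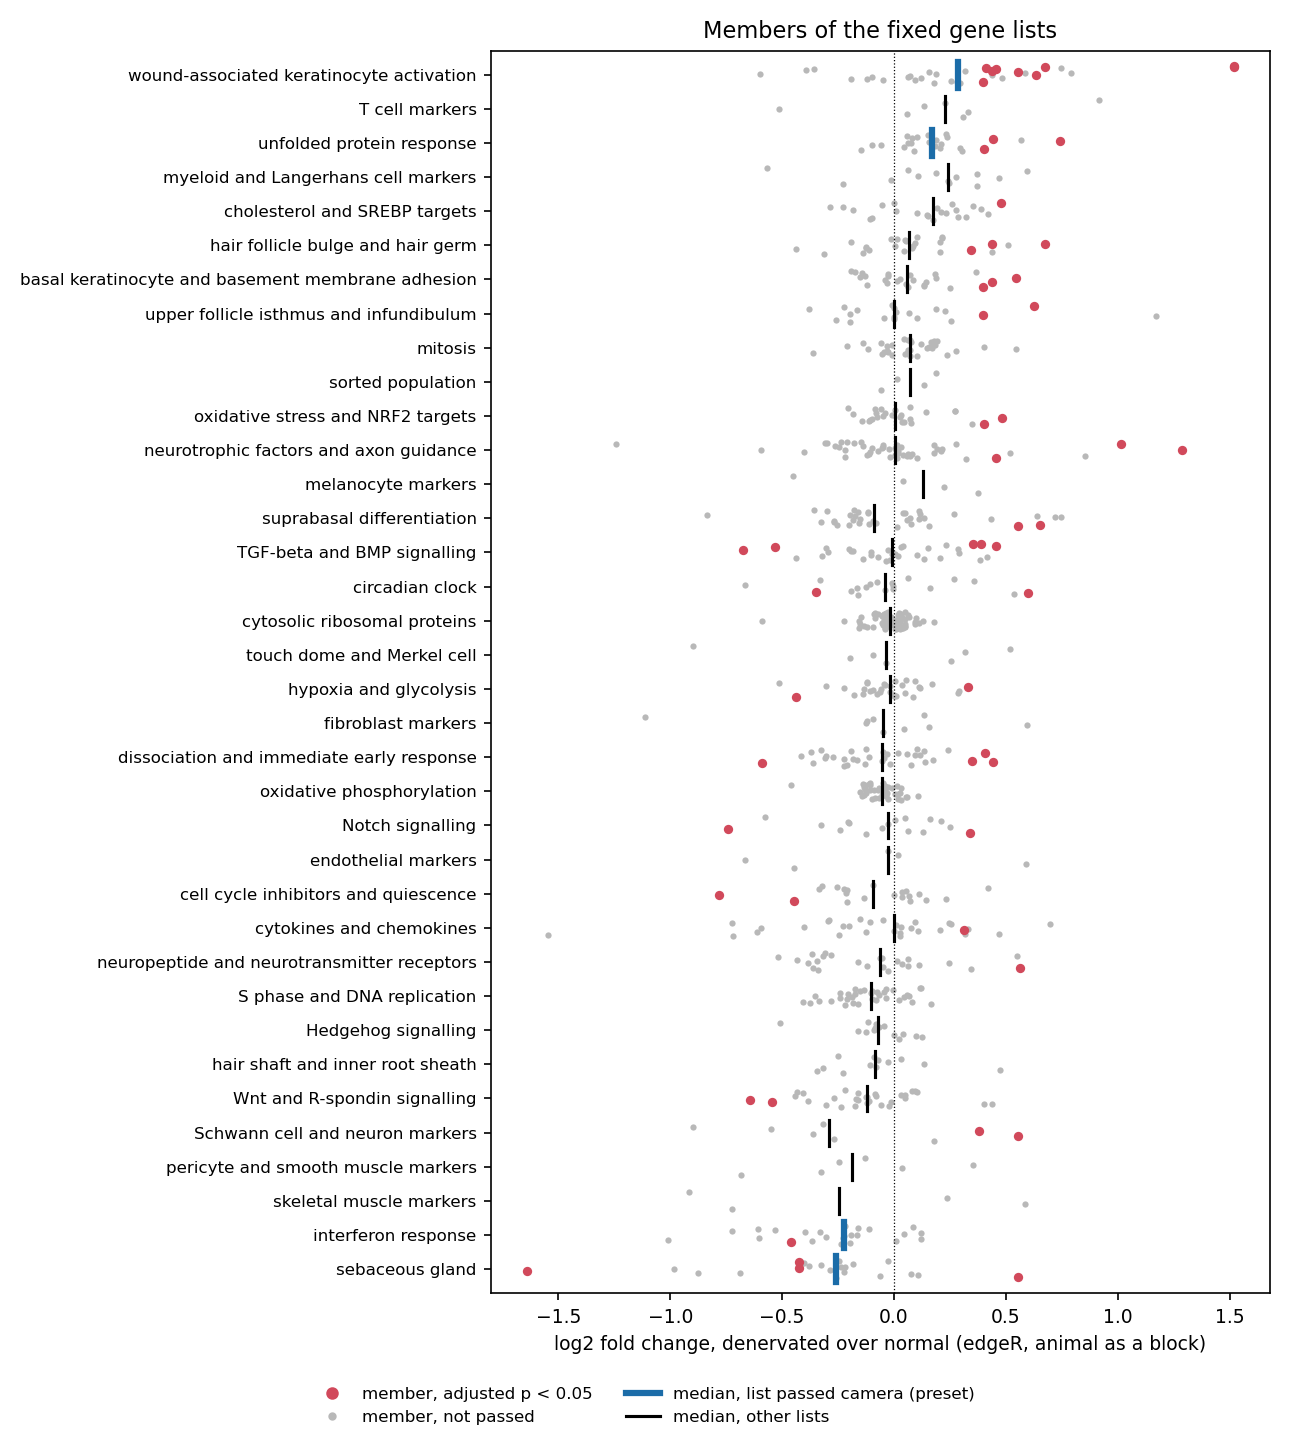
Paired log2 fold change (horizontal axis, denervated over normal, edgeR with the animal as a block) of every tested member of 36 gene lists, ordered by mean change, with members that passed in red, others in grey and a bar at each median. Blue bars mark the 4 lists called by camera with a preset correlation of 0.01, of which the wound-associated list has 9 members that rose and the sebaceous gland list 3 that fell.

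No summed marker list of another cell type could pass the exact permutation test, whose smallest p is 0.1 with 3 libraries per side. The filter on low counts, that is, expression in these libraries, kept 9 fibroblast, 5 endothelial, 6 pericyte, 13 myeloid, 7 T cell, 8 Schwann cell and neuron, 4 melanocyte and 4 skeletal muscle markers. In the paired fit 2 of these passed, Mbp and Pmp22. The fibroblast collagen Col1a2 did not exceed 1.59 CPM and Col1a1 1.79 CPM in any library. Summed CPM of all 22 fibroblast markers was 1285 ± 53.6 on the normal and 1192 ± 96.1 on the denervated side, lower in 3 of 3 animals. The sum of 18 endothelial markers differed by a log2 ratio of −0.32, and that of 14 pericyte and smooth muscle markers stood at 179 ± 4.87 and 145 ± 22.0 CPM, both lower in 3 of 3 animals. Sums were 175 ± 37.1 and 191 ± 5.86 for 22 myeloid and Langerhans cell markers and 122 ± 12.7 and 132 ± 31.8 for 15 T cell markers. The 23 Schwann cell and neuron markers summed to 600 ± 35.1 and 685 ± 20.4, higher in 3 of 3 animals, while the mean log2 fold change of its 8 tested members was −0.14. In that list Mbp (95.6 ± 2.84 to 125 ± 5.32 CPM) and Pmp22 (96.2 ± 8.45 to 143 ± 33.5 CPM) rose in the paired fit, Pmp22 by 0.36 without animal 890 against 0.55 with it, while Sox10, the Schwann cell transcription factor, did not exceed 0.0483 CPM in any library. Melanocyte, skeletal muscle, adipocyte, erythroid and touch dome sums differed by log2 ratios of −0.06, −0.16, 0.02, −0.09 and 0.19, with the erythroid sum lower and the touch dome sum higher in 3 of 3 animals. Over these 11 sums the smallest exact permutation p was 0.1, the lowest that the design allows, with Benjamini-Hochberg adjusted values of 0.367 or more. The endothelial, pericyte and Schwann cell sums reached that lowest p, so the test cannot decide whether they differ. Single genes made up most of some sums. On the normal and denervated sides, after TMM scaling, Gsn of the fibroblast list stood at 931 and 857 CPM and Notch3 of the pericyte list at 125 and 101. Thy1 of the T cell list stood at 111 and 124 CPM, and Erbb3 of the Schwann cell list at 355 and 401. The sums of these lists therefore follow those genes and do not measure amounts of other cells.

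Beyond the lists, the genes with the largest changes that passed in the paired fit were picked by the same rule of size and direction after the counts of calls had been seen. Among those higher, Cgref1, an EF-hand gene, went from 1.81 ± 0.191 to 7.06 ± 7.24 CPM, but its log2 fold change was 0.76 without animal 890 (adjusted p = 0.407), against 1.64 with it. Fhl2, a LIM domain cofactor, rose in each animal by between 1.15 and 1.73 on the log2 scale (1.35 ± 0.18 SE, adjusted p = 0.00445). Nup210l (0.92 ± 0.23 SE), Ubash3b (0.86 ± 0.12 SE), the cofilin phosphatase gene Ssh1 (0.84 ± 0.13 SE), the decoy receptor gene Tnfrsf23 (0.81 ± 0.15 SE) and the YAP partner Tead4 (0.80 ± 0.17 SE) rose as well. Nup210l was not called without animal 892, at 0.53. Among those lower were Lsmem1 (−1.12 ± 0.23 SE), Lysmd1 (−0.98 ± 0.24 SE), the mitochondrial polymerase subunit gene Polg2 (−0.88 ± 0.20 SE), Zkscan8 (−0.85 ± 0.12 SE), Serpinb3b (−0.84 ± 0.18 SE), Ccdc167 (−0.74 ± 0.17 SE), the arrestin gene Arrdc3 (−0.73 ± 0.11 SE), Sema4c (−0.73 ± 0.13 SE) and H2-Bl (−0.71 ± 0.15 SE). Serpinb3b and H2-Bl belong to families of near-identical genes, whose reads may be shared. In the estimated counts the paired log2 fold change of Serpinb3b was −0.89, while that of H2-Bl was 0.00, which makes the value of H2-Bl uncertain.

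The genes closest to the threshold without the block, none of which passed there, included Mast4, Fhl2, Tsc22d2 and Kdm6b among those higher and Arrdc3, Zkscan8, Klhdc8b, Axin2 and Il20rb among those lower. Mast4 stood at 432 ± 35.5 and 642 ± 14.9 CPM and the histone demethylase gene Kdm6b at 445 ± 20.4 and 623 ± 16.2 CPM, differences larger than the spread between libraries. In the paired fit these 9 passed, with adjusted p from 0.00445 for Fhl2 to 0.0127 for Klhdc8b. Of 72 genes picked by the rule that passed in the paired fit, 72 kept their direction when each animal was left out. This was no separate test, since 425 of the 426 called genes moved the same way in 3 of 3 animals. Such genes keep their direction almost by selection. With library totals in the blocked edgeR fit, 54 of all 116 picked genes passed, so some of the 72 calls rest on the TMM factors. DESeq2 without the block called 39 of the 72. With the block it called 46, gave no adjusted p for 20, Mmp10, Mmp13, Fhl2 and Gadd45g among them, and did not call 6, which were Hes1, Sox9, Fabp5, Id3, Irf1 and Socs3. In edgeR the call held without each of the 3 animals for 32, including Nrg1, Fosl1, Mmp3, Mmp10, Mmp13, Axin2, Hes1 and Cry1. Without animal 890 the call was lost for 21, among them Cgref1, Tead4, Lysmd1, Polg2, H2-Bl, Cd44, Itga2, Prdm1, Cldn1, Wnt3a, Nfkb2, Irf1, Klf6, Egr3, Fosb, Asns, Chac1, Srxn1 and Per1. Without animal 892 it was lost for 29, among them Klhdc8b, Nup210l, Lsmem1, Lysmd1, Polg2, Serpinb3b, Ccdc167, Sox9, Cldn1, Fabp5, Wnt3a, Maml1, Tgfbr2, Id3, Gadd45b, Nfkb2, Irf1, Socs3, Fosb, Ddit4, Hk2, Xbp1, Chac1, Txnrd1, Srxn1, Per1 and Mbp, and without animal 899 for 4, which were Scd3, Serpinb3b, Sox9 and Fabp5.

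The authors' deposited table of log2 fold changes holds 24972 genes, of which 6752 have an adjusted p. By the authors' own adjusted p, 491 genes passed 0.05, 445 higher and 46 lower on the denervated side. Of these, 349 were among the 426 genes of the paired edgeR fit, and those 349 had the same sign in both. Of the 426, 39 had no adjusted p there and 38 had one of 0.05 or more. The standard errors in the authors' deposited table differed from those of DESeq2 with the animal as a block, on the estimated counts, by a median absolute log2 ratio of 0.00184, and from those without the block by 0.157. The authors' deposited table gives a log2 fold change of 0.97 for Nrg1 and −0.63 for Axin2.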

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

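Correction for gene length, thinned libraries and all settings of the blocked fit other than the plain edgeR, DESeq2 and fry blocks were chosen after the data were seen. In each case below the cause was not tested unless named.

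Without the block, edgeR called 0 genes under DESeq2 size factors, library totals, a stricter filter, estimated counts, gene length correction, an adjusted p below 0.1 and a fold limit. With no filter it called 137 (128 higher, 9 lower). The animal as a block gave 426 (355 higher, 71 lower), DESeq2 365 (336 and 29), DESeq2 with the block 493 (452 and 41), and limma on log2(TPM + 1) 1, lower, with or without the block.

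In the blocked edgeR fit, DESeq2 size factors gave 471 genes (406 higher, 65 lower), library totals 290 (172 and 118), no filter 987 (692 and 295), a stricter filter 428 (356 and 72), estimated counts 396 (350 and 46), gene length correction 531 (459 and 72), thinned libraries 454 (374 and 80) and an adjusted p below 0.1 820 (603 and 217). Leaving out single libraries or animals, in either fit, gave 0 to 976 genes, 0 to 671 higher and 0 to 305 lower. The unblocked count was 42 (36 higher, 6 lower) without the normal library of animal 899. The blocked count was 385 (292 and 93) without animal 890, 248 (215 and 33) without animal 892 and 976 (671 and 305) without animal 899. With 1 animal fewer, 2 libraries per side carry the test. With 1 library fewer, its animal stands on 1 side only, so differences between animals enter the unblocked values.

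Camera called 4 lists with and without the block, and 0 with an estimated correlation or with fry, each with or without the block. Library totals in the blocked fit gave 7 lists, and leaving out libraries or animals 3 to 8, with 8 in the blocked fit without animal 890 and 8 without animal 899. Over those leave-outs the mean log2 change ran from −0.071 to 0.64 for the wound-associated list, −0.39 to −0.28 for the sebaceous list, −0.43 to −0.13 for the interferon list and 0.11 to 0.28 for the unfolded protein response.

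Of 116 genes picked by the rule for named genes, 109 had a value in each of the 18 alternatives that use every library, and 105 of these kept their sign in all 18. Over all 30 alternatives, 101 of those 109 kept it. Krt5 had a log2 fold change of −0.045 with library totals (−0.049 with the block), −0.0071 with estimated counts (−0.010 with the block) and −0.040 in limma on TPM with or without the block. Lpl stood at −0.030 with library totals in the blocked fit, H2-Bl at 0.00116 with estimated counts in the blocked fit, and Bpgm at 0.021 with gene length correction (0.024 with the block). Leaving out libraries or animals moved Krt25 from −0.83 to 1.71, Tnc from −0.035 to 0.64, Cdon from −0.22 to 0.024, Trpm1 from −1.18 to 0.10, Lpl from −0.31 to 0.36, Bpgm from −0.10 to 0.020, Lgr6 from −0.15 to 0.11, Krt5 from −0.045 to 0.11 and H2-Bl from −0.89 to −0.50. Of these, Krt25 was at −0.78 without animal 892, and the log2 fold change of Trpm1 was −0.96 without animal 899 and 0.033 without the normal library of animal 892. In the blocked fit, Tnc was at −0.022 and Krt5 at −0.027 without animal 890, and Bpgm at 0.0076 and Krt5 at −0.031 without animal 892. Depth limits genes with few counts, since 3 counts equal up to 0.312 CPM in the smallest library.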

Other observations

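The tests of gene length and scaling, those of the wound-associated genes with the bounds for excluding a cause, and the splits of the blocked fit were chosen after the result was seen; the thinning test, the 3 added gene lists in full and the other splits were set before their results.

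Mmp13, Mmp3 and Mmp10 lie in a cluster of matrix metalloproteinase genes on chromosome 9. Their neighbours, chosen after their values were seen, were barely expressed. Mmp1b had a highest count of 39 in any library and did not pass (paired log2 fold change 0.93, edgeR adjusted p = 0.518). The highest counts of Mmp12, Mmp1a, Mmp27 and Mmp20 were 13, 17, 12 and 1, and Mmp7 and Mmp8 had 0 counts. The labels describe the removal of nerves on the left side and no sham dissection on the right, so the effects of losing nerves and of dissecting the skin were not separated by the design, and this was not tested.

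Most genes called with the animal as a block were higher on the denervated side, 83.3% of 426. Lower read totals on that side do not account for this, since 82.4% were higher with all libraries thinned to the smallest total. A trend with gene length does not either, although the paired log2 fold change correlated with length across genes, which are not independent (Spearman 0.15), because 86.4% were higher after its removal. With library totals in place of TMM factors, 59.3% of the called genes were higher. The excess of higher genes may therefore come in part from the scaling between libraries, and which scaling is right was not tested.

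The list of wound-associated keratinocyte genes had a median log2 change of 0.29 on the denervated side, with 9 of 32 members called. Its call was lost with an estimated correlation (adjusted p = 0.992), and its unblocked mean was −0.01 or −0.07 without 1 library. Those 2 means also carry differences between animals, since 1 animal then stands on 1 side only. With the block the call held without each animal in turn (means 0.20, 0.50 and 0.26). The list passed without the block in 5 of 6 splits that leave an animal's libraries together, which carry differences between animals, and in 1 of 3 other splits that part the animals, with or without the block. Whether the list moved as a whole is therefore uncertain. The median of the dissociation response lay lower (difference −0.34, 95% bootstrap interval over genes −0.57 to −0.17), by more than the SD of its members (0.24). Bootstrap intervals over genes take genes as independent and carry no variation between animals. In these libraries 22 members of the dissociation response pointed down and 13 up, which argues against a rise of that response as a whole. Its members went both ways, with Klf6, Egr3 and Fosb called higher at 0.44, 0.35 and 0.40 and Socs3 lower at −0.59, so a change in part of it stays open. For the fibroblast markers the difference was −0.34 (−0.53 to −0.05), within the SD of their members (0.45), so it decides little alone. Col1a1 and Col1a2, abundant in fibroblasts, reached at most 1.79 CPM in any library, while the called wound-associated genes rose by a sum of 699 CPM, which argues against fibroblasts as the source. Myeloid and Langerhans cell markers differed by −0.046 (−0.32 to 0.15), so carry-over of immune cells stays open. Among the markers of these cells, Cd74 at 56.8 ± 15.8 and 67.3 ± 5.98 CPM, Cd207 at 15.4 and 17.4 CPM and H2-Ab1 did not pass. Their RNA was present on both sides after the sort for Itga6 and tdTomato, so the sort alone does not exclude such cells. A response of the keratinocytes to nerve loss or to the dissection stays open and untested.

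Hypotheses from single genes, all chosen after their values were seen, were tested on lists without those genes. Tead4 and F3 prompted a list of YAP and TAZ targets, which was higher (21 genes, mean log2 fold change 0.08, camera with the block, adjusted p = 0.0121), but not called with an estimated correlation (adjusted p = 0.213). Of its members 13 pointed up, and Wwc1, Dock5 and Tead1 were called. With library totals its mean was 0.02 (adjusted p = 0.00771), and 1 of 3 other splits that part the animals passed as well. Phlda1 and Fosl1 prompted a list of ERK pathway output, which passed or missed with the setting (13 genes, 0.12, adjusted p = 0.0501 with the block and 0.0235 without it). With library totals and the block its mean was 0.06 (adjusted p = 0.0361), and with an estimated correlation the adjusted p was 0.213. Its called members were Epha4 and Dusp6, and the value of Epha4 had been seen. Without Epha4 and 2 more genes of other lists, chosen after this result, 10 genes were left and the ERK list did not pass (adjusted p = 0.146 with the block, 0.0988 without it and 0.131 with library totals). The YAP and TAZ list, without 4 genes of other lists, passed camera with the block (17 genes, 0.11, adjusted p = 0.00473), but not with an estimated correlation (0.292). With library totals its mean was 0.05. The removed genes Ctgf, Cyr61 and Tgfb2 pointed down (paired log2 fold changes −0.14, −0.30 and −0.02) and Gadd45a up (0.42), and none was called. Their removal raised the mean from 0.08 to 0.11, so the shorter list is no stricter check. Tsr1, Ddx21 and Ccdc86 prompted a list of ribosome biogenesis, which was higher (27 genes, 0.20, adjusted p = 3.69e-07, and 0.14 with library totals), but not called with an estimated correlation (adjusted p = 0.213). In it 25 genes pointed up and 5 were called higher, Gnl3, Wdr43, Noc3l, Rrp12 and Nolc1. This list passed in 1 of 3 other splits that part the animals and, without the block, in 5 of 9 other splits, so its call may reflect genes that vary together between libraries.

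Splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. Without the block, denervated against normal gave 0 genes and the highest other split 3. Among the 4 splits that part each animal's libraries, only the real one, 1 of 4, gave 426 genes with the block, and the highest other gave 0. Each of the others swaps the sides of 1 animal, so a difference shared by the animals becomes spread there and lowers the count. The 0 is therefore no independent measure of chance. For gene lists without the block, the real split gave 4, fewer than any other split, which gave 5 to 12. The number of lists called therefore does not set denervated against normal apart from other groupings. The 3 other splits that part each animal's libraries gave 7, 7 and 5 lists. With the block, run after these values were seen, they gave 13, 7 and 7, against 4 for the real split. Without the block the sebaceous list passed in 1 of the 9 other splits, the interferon list in 2, the unfolded protein response in 4 and the wound-associated list in 6. With the block the sebaceous list passed in 2 of the 3 and each of the other lists in 1 of the 3.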
